A study of Homo sapiens with 8 samples.

How the data were processed

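Messenger RNA levels were measured by RNA sequencing in 8 libraries: 2 each of wild-type (WT) and DJ-1-deficient human mesenchymal stem cells (hMSCs, passage 3) and of WT and DJ-1-deficient human neural stem cells (hNSCs, passage 5). Per the labels, both lineages were derived from embryonic stem cells, WT cells came from the H9 line and the deficient cells from 1 line. The labels' protocols state TRIzol extraction, removal of genomic DNA and the NEBNext Ultra RNA library kit. They speak of duplicates without saying whether these were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Lineage went together with culture medium and passage. The column headers of the hMSC files also carry a prefix that those of the hNSC files lack, so separate sequencing of the lineages cannot be ruled out.

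The deposited files hold raw read counts per gene, 57905 gene identifiers per library, with no normalization. HISAT2, HTSeq and StringTie and the genome build hg19 are named for every sample, per the submitters' processing notes, without versions. The strand setting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Each file ends with 5 entries that are not genes; they were left out of library sizes and tests. Of the reads that fell on a gene, on no annotated feature or on several genes, 5.95% to 6.57% in hMSCs and 13.26% to 14.14% in hNSCs lay on no feature, and 8.21% to 8.74% over all libraries were ambiguous. Gene counts per library were 7037075 and 11494742 in WT hMSCs, 14855976 and 8554800 in deficient hMSCs, 10750794 and 9282493 in WT hNSCs, and 10082563 and 12609148 in deficient hNSCs. Gene symbols came from a reference table that matched 52338 identifiers by their stable ID. The reference genome at hand was of another build, so no coordinates are given.

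Groups were taken from the labels. Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group (16596 genes tested), and the quasi-likelihood test on 1 fit of the 4 group means over all 8 libraries, with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 were called. The contrasts were deficient minus WT in hMSCs, the same in hNSCs, the difference of those differences (hNSCs minus hMSCs), and the mean of the hNSC groups minus the mean of the hMSC groups. Levels are normalised read counts (CPM). Standard errors (SE) of log2 fold changes were the size of the change divided by the square root of the quasi-likelihood F statistic. They are too small for large changes where a group had few counts. A gene was counted as bounded within 2-fold when its 95% interval, built from this error, lay between -1 and 1 on the log2 scale. The mean count per group of 2 libraries limits what could be seen in weakly expressed genes. All intervals cover at most the spread between libraries and counting error, and less than that for large changes with few counts.

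The gene lists, the tests of genes and lists, the contrasts and the rule for naming genes were fixed before the data were examined. Some tests of possible explanations were chosen afterwards and are named as such where they are given. The rule named PARK7 first. For each genotype contrast it then took the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group of that lineage, both deficient libraries on the same side of both WT libraries, and a symbol that was not a clone name. It took 5 on each side for the difference between lineages and 8 for the lineage contrast, and up to 4 members with the smallest p in each gene list described. In lists that the list test did not call, members whose own call was lost without 1 library are counted and mostly not named. The results of some genes that the rule took are not reported here. Genes with a near-identical copy, a pseudogene or an overlapping gene, or with over 8-fold differences between replicates, are given as uncertain.

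The 31 lists, each with at least 5 tested members, were tested with limma's camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals. They covered NRF2 targets, antioxidant enzymes, mitochondrially encoded mRNAs, the nuclear-encoded respiratory chain, genes of Parkinson's disease and mitophagy, glycolysis and hypoxia, p53 targets, the cell cycle, senescence and its secretory phenotype, apoptosis regulators, the unfolded protein response, the heat shock response, interferon-stimulated genes, cholesterol synthesis, the extracellular matrix, immediate early genes, WNT targets, TGF-beta and BMP targets, neighbours of PARK7 on its chromosome, HOX genes and forebrain and midbrain patterning genes. The remaining lists were markers of mesenchymal stem cells, neural stem cells, neurons, glia, neural crest, pluripotent cells, smooth muscle, bone, cartilage and fat, endothelium and blood, and epithelium and endoderm. DACH1, NEFL and PECAM1 had no match by symbol and entered no list. With the correlation estimated, the list test rests on the 4 residual degrees of freedom. It then called no list in any contrast, not even between lineages, so its lack of calls cannot decide which lists differ.

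The fit was tested on simulated counts drawn from the means and library sizes of the real libraries, with 5 simulations of 200 changed genes per genotype comparison. In the hMSC comparison 65.2%, 80.4%, 95.2% and 98% of genes changed by 1.5-, 2-, 4- and 8-fold were recovered, and 7.5% of calls were false. In the hNSC comparison the shares were 59.2%, 80.4%, 94.4% and 96.8%, with 6.3% false calls. The list with a simulated shift, 1.5-fold or 0.58 on the log2 scale, was called in 5 of 5 simulations in both comparisons. Of lists without a shift, 0 of 123 (hMSCs) and 0 of 130 (hNSCs) were called. The lists called in the real genotype contrasts had smaller medians, such as 0.15 for NRF2 targets in hMSCs and -0.3 for the matrix list in hNSCs. Recovery of such small list shifts, or of gene changes under 1.5-fold, was not tested. Each gene was drawn independently, whereas the estimated correlation of the real matrix list was 0.45 in the hMSC contrast. False calls of lists with correlated genes were therefore not tested. Changed genes were taken from those above a minimum count, so recovery does not cover the weakest genes.

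Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, each lineage fitted alone, the replicate number as a block, protein-coding genes only, a 2-fold minimum, an estimated correlation in the list test, and each library left out in turn, which assumes that the remaining library of its group varies like the other groups. A fit without features that differed over 8-fold between the 2 libraries of a group was added after the data had been seen. Sequence sharing was measured as the percent of 100-base windows, every 25 bases along the longest transcript, that also occurred in another gene of the GENCODE 29 transcripts. Figures were drawn with matplotlib 3.10.9.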

Results

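Transcriptomes were compared between WT and DJ-1-deficient cells of 2 human stem cell types, hMSCs and hNSCs, to ask whether loss of DJ-1 alters stem cells at rest. DJ-1, encoded by PARK7, is a small protein that protects cells against oxidative stress, and its loss causes an inherited form of early-onset parkinsonism. H9, the WT source, is an established human embryonic stem cell line. The hMSCs were grown in serum and FGF2, and the hNSCs without serum, with inhibitors of the TGF-beta receptor and of the kinase GSK3, which restrains WNT signalling. There were 4 groups with 2 libraries each, with 7037075 to 14855976 gene counts per library in hMSCs and 9282493 to 12609148 in hNSCs. Replicate libraries differed by more than sampling noise in every group, with a chi-square per degree of freedom of 1.905 to 2.894, so each was kept as its own library. Between genotypes the same measure was 7.137 to 9.719 in hMSCs and 2.943 to 3.39 in hNSCs.

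PARK7 (ENSG00000116288) was low in all 4 deficient libraries. In hMSCs its normalised read count was 246.74 and 250.66 CPM in the WT libraries and 6.48 and 9.14 CPM in the deficient libraries, a log2 difference of -5.05 ± 0.10 (SE, adjusted p = 2.56e-31). In hNSCs the values were 149.62 and 159.64 CPM against 16.88 and 15.97 CPM, a log2 difference of -3.24 ± 0.09 (adjusted p = 2.92e-27). The transcript left was 3% of the WT level in hMSCs (95% interval 2.6% to 3.5%) and 10.6% in hNSCs (9.4% to 12%). The hMSC interval is likely too narrow, because the deficient libraries held only 82 and 70 counts. The fall was smaller in hNSCs by 1.81 ± 0.15 on the log2 scale (adjusted p = 6.04e-11). CHCHD2, which encodes a mitochondrial protein also linked to inherited parkinsonism, went the other way: it had 4 and 5 counts in the WT libraries of each lineage (0.33 to 0.64 CPM) and 107.23 to 143.7 CPM in the deficient libraries. Its log2 difference was 7.96 in hMSCs and 8.07 in hNSCs (edgeR adjusted p = 2.36e-30 and 1.63e-30). The computed error, 0.17 in both, is too small to hold the counting error of so few WT counts. CHCHD2 has processed pseudogenes, and the labels name only 1 deficient line.

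**Figure D1:**
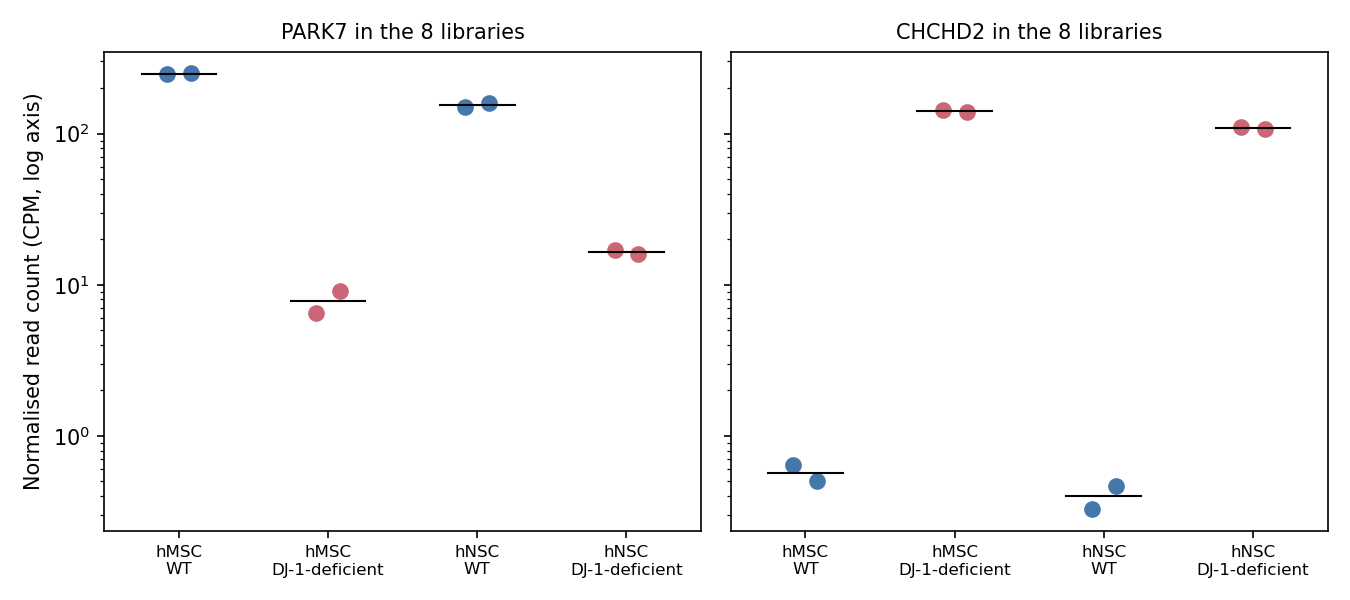
Normalised read count (CPM, log axis) of PARK7 (left) and CHCHD2 (right) in each of the 8 libraries by group; points are libraries and the horizontal lines are group means. PARK7 lies between 149.62 and 250.66 CPM in WT libraries and between 6.48 and 16.88 CPM in deficient libraries, while CHCHD2 lies at 0.64 CPM or less in WT libraries and at 107.23 CPM or more in deficient libraries.

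In deficient hMSCs, SYT11, TENM2 and RELN were among the genes that fell most after PARK7, and PRRX2, SOX5 and DLK1 among those that rose most. SYT11, a regulator of vesicle traffic, fell from 34.15 ± 0.97 to 4.96 ± 0.19 CPM (SD, n = 2 per group; log2 difference -2.80 ± 0.13, adjusted p = 1.96e-18). TENM2, a synaptic adhesion protein, fell from 29.67 ± 0.75 to 9.01 ± 2.22 CPM, and RELN, a secreted guide of neuron migration, from 10.64 ± 1.46 to 3.26 ± 1.09 CPM. LOXL4, which crosslinks collagen, fell by 1.84 on the log2 scale (SE 0.32). The zinc finger gene ZNF880 fell by 2.04 (SE 0.33) and the sulfotransferase gene SULT1B1 by 1.51 (SE 0.25). PRRX2, a mesenchymal homeobox factor, rose from 4.32 ± 0.44 to 20.03 ± 1.40 CPM (log2 difference 2.19 ± 0.22, adjusted p = 1.8e-09). SOX5, a factor of cartilage development, rose from 1.54 to 6.32 CPM and DLK1, an inhibitor of fat cell differentiation, from 7.48 to 24.84 CPM. PWWP3B (log2 difference 2.04 ± 0.35), the channel gene CALHM2 (1.94 ± 0.32) and the microtubule-associated MTUS1 (1.86 ± 0.21) rose as well.

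Other genes that the naming rule took in hMSCs were uncertain or lost their call without 1 library. FAM156B (log2 difference -1.68 ± 0.32), RPSAP19 (-1.74 ± 0.36), TSSC2 (-1.72 ± 0.23), CUTA (5.49 ± 0.58), CEBPZOS (-1.71 ± 0.18) and PCDHGA10 (2.03 ± 0.23) share sequence with other genes, are pseudogenes or overlap another gene, so reads cannot be assigned to them with certainty. TIMM23B (-3.52 ± 0.55) and DDT (5.19 ± 0.97) each differed over 8-fold between the 2 libraries of a group. The TIMM23B call was lost without WT replicate 2 (adjusted p = 0.773, range over all alternatives 1.75e-31 to 0.773). The FAM156B call was lost without WT replicate 1 (0.621, range 3.49e-16 to 0.621). RPSAP19 lost its call without WT replicate 1 (0.533) or deficient replicate 1 (0.0564), with a range from 3.72e-08 to 0.533. TIMM23B (0.114), FAM156B (0.198) and RPSAP19 (0.131) were not called by the DESeq2 Wald test. HGF, a growth factor of epithelial cells, stood at a log2 difference of 1.73 ± 0.40 and lost its call without WT replicate 1 (0.0681) or deficient replicate 2 (0.108, range 0.000189 to 0.108). TMEM132D, at 1.80 ± 0.31, lost its call without WT replicate 2 (0.0579, range 1.34e-06 to 0.0579).

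Genes induced by the antioxidant-response factor NRF2 rose as a group in deficient hMSCs: 7 of the 21 tested rose, 0 fell and 14 did not pass the test (8 rose when adjusted over the list alone; camera adjusted p = 6.4e-07, and adjusted p = 0.293 with an estimated correlation). The cystine transporter SLC7A11 went from 183.43 ± 9.84 to 270.67 ± 20.65 CPM (SD, n = 2; log2 difference 0.57 ± 0.06). The quinone reductase NQO1 went from 429.95 ± 25.63 to 603.63 ± 20.79 CPM (0.49 ± 0.06). The pentose phosphate enzyme TKT rose by 0.41 ± 0.05. Of the 13 mitochondrially encoded mRNAs, 4 rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 8.48e-05, and adjusted p = 0.324 with an estimated correlation). MT-ATP6, a subunit of ATP synthase, stood at 0.21 ± 0.05. The call of MT-CO1 was lost without WT replicate 1 (0.0584) or deficient replicate 1 (0.0856, range 1.17e-05 to 0.0856). Without the same libraries MT-CO3 was lost (0.241 and 0.215, range 0.000474 to 0.241). MT-CYB was lost without them (0.237 and 0.398) and without WT replicate 2 (0.0656, range 0.000322 to 0.398). Mitochondrial genes took 2.95% of gene counts in both WT libraries and 3.23% and 3.32% in the deficient libraries. Among 26 extracellular matrix genes 8 rose and 6 fell (10 and 6 adjusted over the list alone), with the collagens COL3A1 at 1.17 ± 0.05, COL6A3 at 0.51 ± 0.05 and COL6A1 at 0.44 ± 0.05 and the matricellular THBS1 at -0.66 ± 0.05. The matrix list passed the test upwards at an adjusted p of 0.0417 (adjusted p = 0.699 with an estimated correlation). Its call was lost with the replicate number as a block. That call was lost without the filter on low counts (0.0728) and without any 1 of 7 libraries: 0.143 and 0.0671 without WT hMSC replicates 1 and 2, 0.568 without deficient hMSC replicate 1, 0.103 and 0.106 without WT hNSC replicates 1 and 2, and 0.103 and 0.0969 without deficient hNSC replicates 1 and 2 (range over all alternatives 3.31e-05 to 0.699).

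Of 21 unfolded protein response genes, 5 fell and 0 rose in deficient hMSCs (6 adjusted over the list alone; camera adjusted p = 8.35e-06, and adjusted p = 0.293 with an estimated correlation). Those named were PSAT1 (serine synthesis, log2 difference -0.99 ± 0.08), CHAC1 (glutathione breakdown, -1.16 ± 0.23), the transcription factor ATF4 (-0.27 ± 0.06) and ASNS (asparagine synthesis, -1.22 ± 0.12). ASNS is uncertain because 79.1% of its windows also lie in another annotated gene. Without WT replicate 2 the calls of CHAC1 (0.0992, range 7.34e-05 to 0.0992) and ATF4 (0.0675, range 1.51e-05 to 0.0675) were lost. Of 23 p53 targets, 4 fell and 0 rose (8 adjusted over the list alone; camera adjusted p = 1.29e-05, and adjusted p = 0.293 with an estimated correlation). The secreted stress factor GDF15 fell from 158.34 ± 3.15 to 103.92 ± 3.73 CPM (-0.61 ± 0.08). The cell cycle inhibitor CDKN1A stood at -0.20 ± 0.05, RRM2B at -0.26 ± 0.07 and PLK3 at -0.39 ± 0.10. CDKN1A lost its call without WT replicates 1 (0.066) or 2 (0.202) or deficient replicate 2 (0.112, range 0.000418 to 0.202). RRM2B lost its call without the same libraries (0.128, 0.148 and 0.119, range 0.00344 to 0.148). PLK3 lost its call without WT replicates 1 (0.114) or 2 (0.127) or deficient replicates 1 (0.0699) or 2 (0.0759, range 0.0114 to 0.127), and in the DESeq2 Wald test (0.0842). Of 16 TGF-beta and BMP targets, 6 fell and 1 rose (8 and 5 adjusted over the list alone; camera adjusted p = 1.29e-05, and adjusted p = 0.294 with an estimated correlation). They included the matricellular proteins CCN2 (-0.88 ± 0.06) and CCN1 (-0.65 ± 0.06), the signalling inhibitor PMEPA1 (-0.77 ± 0.10) and the actin-binding TAGLN (-0.47 ± 0.06).

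WNT targets fell in deficient hMSCs, with 3 of 13 lower and 0 higher (4 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.294 with an estimated correlation). The cyclin CCND1 fell by 0.44 (SE 0.05), and the WNT inhibitors NKD1 and DKK1 stood at -2.77 ± 0.79 and -0.45 ± 0.13. NKD1 lay near 0 in hMSCs, with 14 counts over all hMSC libraries (mean 0.4 CPM), so its fold change rests on few reads. The list was no longer called without WT replicate 1 (0.0689) or deficient replicate 2 (0.0543; range over all alternatives 0.00883 to 0.294). NKD1 lost its call without WT replicate 2 (0.473) or deficient replicates 1 (0.267) or 2 (0.0687; range 0.0247 to 0.473). DKK1 lost its call without WT replicates 1 (0.101) or 2 (0.253) or deficient replicate 1 (0.275; range 0.00782 to 0.275). Neither NKD1 (0.141) nor DKK1 (0.0977) was called by the DESeq2 Wald test, and NKD1 was also lost without the filter on low counts (0.0506).

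**Figure D2:**
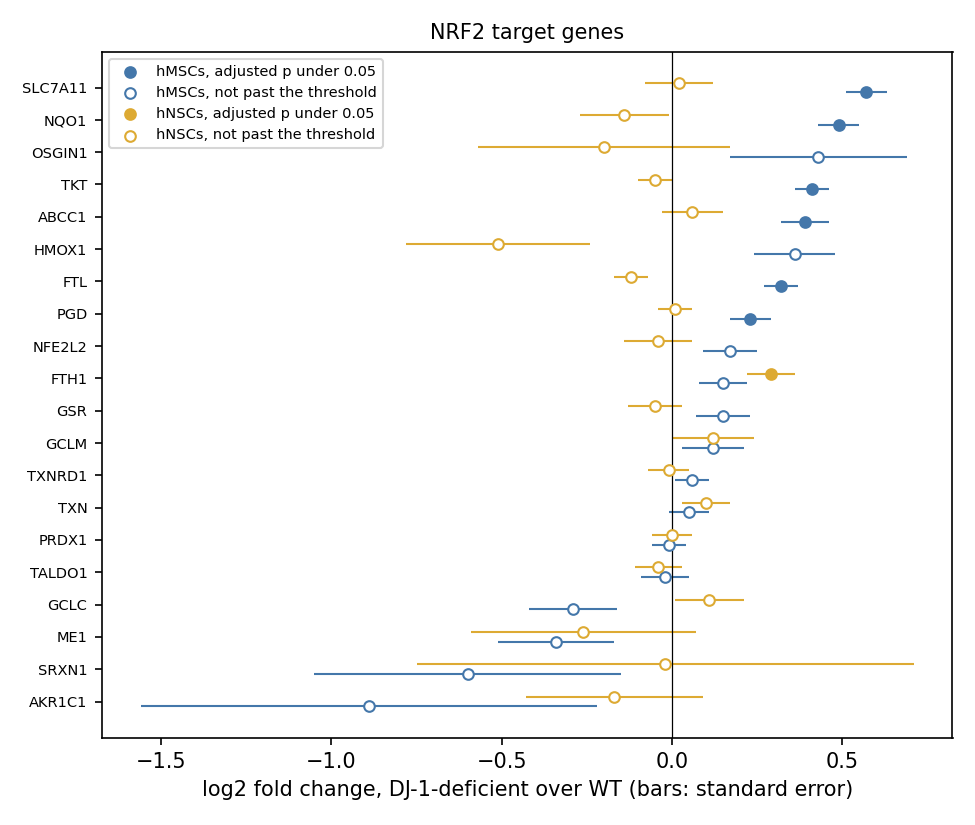
Log2 fold change of deficient over WT cells for 20 of the 21 tested NRF2 targets in hMSCs (blue) and hNSCs (yellow), with bars for the standard error; filled points passed an adjusted p under 0.05. In hMSCs 6 genes are filled, from PGD at 0.23 to SLC7A11 at 0.57, and in hNSCs 1 gene, FTH1, is filled at 0.29.

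The other 24 lists were not called in hMSCs, with some single members that moved. Mesenchymal stem cell markers went both ways (6 higher and 3 lower of 19, adjusted p = 0.16), with the growth factor receptor PDGFRA at 0.65 ± 0.07, the homeobox factor PRRX1 at 0.47 ± 0.07 and the adhesion protein ALCAM at -0.31 ± 0.06. Smooth muscle markers did too (2 higher and 6 lower of 12, adjusted p = 0.131), with the actin ACTG2 at 1.01 ± 0.07 and the contractile regulators MYLK at 0.73 ± 0.07 and CALD1 at -0.45 ± 0.05. Of the senescence list 3 of 20 rose and 3 fell (adjusted p = 0.81), among them the growth factor binding protein IGFBP5 at 0.51 ± 0.05. SOD3, the extracellular superoxide dismutase, rose by 1.57 ± 0.25 as the 1 called of 19 antioxidant enzymes (adjusted p = 0.343). In the list of Parkinson's disease and mitophagy, 1 of 21 rose and 1 fell (adjusted p = 0.835). OPTN, an autophagy receptor, stood at -0.33 ± 0.09 and lost its call without WT replicates 1 (0.23) or 2 (0.0975) or deficient replicate 2 (0.184; range over all alternatives 0.0113 to 0.23) and in the DESeq2 Wald test (0.109).

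In the remaining lists of the hMSC comparison the called members were few. The glycolysis and hypoxia list had 2 lower of 24 (lactate dehydrogenase LDHA at -0.53 ± 0.05 and BHLHE40 at -0.73 ± 0.11, adjusted p = 0.37). Neural stem cell markers had 2 higher and 1 lower of 19 (adjusted p = 0.484, with the adhesion protein CDH2 at -0.78 ± 0.06). Neural crest markers had 3 higher and 1 lower of 12 (0.132), and cholesterol synthesis 1 higher and 2 lower of 20 (0.343). The cell cycle (28 tested, adjusted p = 0.611), apoptosis regulators (20, 0.31), immediate early genes (17, 0.267) and neuron markers (17, 0.835) each had 1 higher and 1 lower. There was 1 higher gene among interferon-stimulated genes (22 tested, 0.343), glia markers (9, 0.484), bone, cartilage and fat genes (7, 0.525) and forebrain and midbrain patterning genes (12, 0.484). There was 1 lower among epithelial and endoderm markers (9, 0.423). None was called among nuclear-encoded respiratory chain genes (30, 0.519), the heat shock response (14, 0.358), pluripotency markers (6, 0.525), endothelial and blood markers (7, 0.484), HOX genes (10, 0.104) or PARK7 neighbours (8, 0.835).

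By the edgeR test, 929 of 16596 genes differed in hMSCs, 504 higher and 425 lower in deficient cells (2718 at an unadjusted p under 0.05). Most differences were small, with a median size of 0.49 on the log2 scale, and 168 called genes differed at least 2-fold, 92 higher and 76 lower. For 71.5% of tested genes the 95% interval lay within 2-fold. Without WT replicate 2 the count was 559 and without WT replicate 1 it was 582, and the DESeq2 Wald test called 589. The split was 295 higher and 418 lower without deficient replicate 1, and 581 and 289 without replicate 2.

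In deficient hNSCs, the collagens COL3A1 and COL1A1 fell, and LHX2, DMRTA2 and FEZF2 were among the genes that rose most. COL3A1 fell from 167.89 ± 3.79 to 51.12 ± 1.18 CPM (SD, n = 2; log2 difference -1.72 ± 0.07, adjusted p = 1.79e-21) and COL1A1 from 65.66 ± 5.49 to 19.76 ± 1.59 CPM (-1.74 ± 0.08, adjusted p = 3.95e-18). COL6A3 (-1.75 ± 0.14), COL1A2 (-0.74 ± 0.07), COL16A1 (-1.58 ± 0.21) and the matrix proteoglycans DCN (-2.22 ± 0.36) and BGN (-1.58 ± 0.20) fell, with the scavenger receptor COLEC12 (-1.68 ± 0.22) and the cytochrome P450 enzyme CYP1B1 (-1.53 ± 0.18). LHX2, a homeobox factor of the early forebrain, rose from 0.70 ± 0.07 to 5.78 ± 0.54 CPM (3.03 ± 0.42, adjusted p = 1.36e-05). The forebrain factors DMRTA2 and FEZF2 rose from 1.82 ± 0.31 to 9.09 ± 0.42 CPM and from 10.96 ± 1.42 to 26.50 ± 0.56 CPM.

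Of 26 extracellular matrix genes, 9 fell and 0 rose in deficient hNSCs (14 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.01e-43, and adjusted p = 0.16 with an estimated correlation). Of the 59 genes lower in deficient hNSCs, 15 were at least 32-fold higher in hMSCs than in hNSCs, or 25.4% against 2.8% of all tested genes. Without the matrix list it was 9 of 50, or 18% against 2.7%. Mesenchymal stem cell markers passed downwards (2 lower and 0 higher of 19, 3 lower adjusted over the list alone; camera adjusted p = 0.00454, and adjusted p = 0.455 with an estimated correlation). They did not pass without WT replicate 2 (0.0982) or deficient replicate 1 (0.103; range over all alternatives 0.00508 to 0.455). Their called members were PRRX1 at -1.61 ± 0.33, lost without WT replicate 1 (0.0595) or deficient replicate 1 (0.155, range 0.000587 to 0.155), and PDGFRB at -0.83 ± 0.20. PDGFRB was lost without WT replicate 1 (0.597) or deficient replicates 1 (0.224) or 2 (0.0711, range 0.00465 to 0.597), and in the fit of the hNSC libraries alone (0.0665). Smooth muscle markers passed downwards (1 lower and 0 higher of 12, 2 lower adjusted over the list alone; camera adjusted p = 0.0054, and adjusted p = 0.357 with an estimated correlation). The 1 called was ACTG2, which fell from 5.24 ± 0.71 to 0.85 ± 0.09 CPM (-2.59 ± 0.29). The call of the list was lost without WT replicate 1 (0.0992) or deficient replicate 1 (0.0582; range 0.00237 to 0.357).

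**Figure D3:**
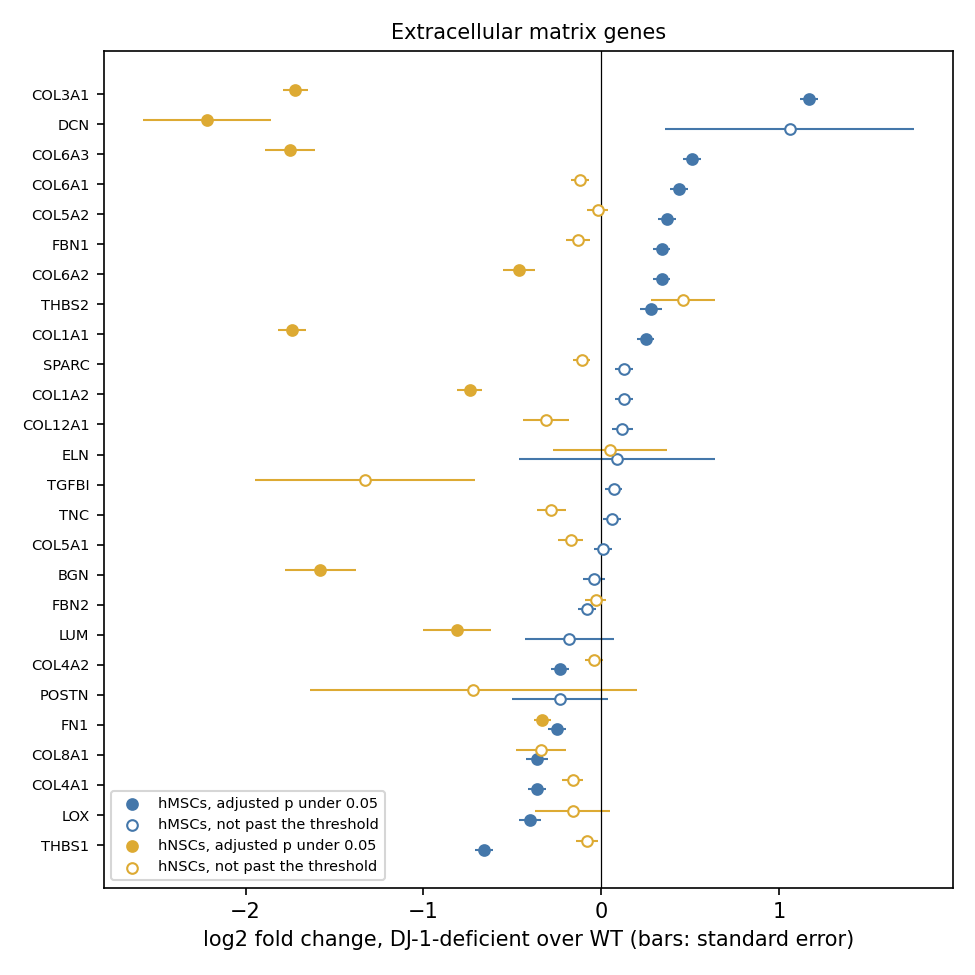
Log2 fold change of deficient over WT cells for the 26 extracellular matrix genes in hMSCs (blue) and hNSCs (yellow), with bars for the standard error; filled points passed an adjusted p under 0.05. COL3A1 lies at 1.17 in hMSCs and -1.72 in hNSCs, and THBS1, the lowest in hMSCs, lies at -0.66.

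Of the 13 mitochondrially encoded mRNAs, 5 rose and 0 fell in deficient hNSCs (10 adjusted over the list alone; camera adjusted p = 2.09e-20, and adjusted p = 0.154 with an estimated correlation). Among them were the complex I subunits MT-ND4L (0.44 ± 0.07), MT-ND3 (0.30 ± 0.05) and MT-ND2 (0.27 ± 0.05) and MT-ATP6 (0.26 ± 0.05). Mitochondrial genes took 2.98% and 3% of gene counts in the WT libraries and 3.28% and 3.37% in the deficient libraries. The DESeq2 Wald test did not call MT-ND4L (0.456, range over all alternatives 1.67e-10 to 0.456). Of 19 neural stem cell markers 4 rose and 0 fell (4 adjusted over the list alone; camera adjusted p = 2.63e-06, and adjusted p = 0.215 with an estimated correlation), among them LHX2 and the zinc finger factors ZIC2 (0.46 ± 0.10) and ZIC1 (0.36 ± 0.08). ZIC2 lost its call without WT replicate 2 (0.214) or deficient replicates 1 (0.13) or 2 (0.0522, range 0.00106 to 0.214). ZIC1 lost its call without the same libraries (0.331, 0.103 and 0.121, range 0.00132 to 0.331). Neither ZIC2 (0.154) nor ZIC1 (0.226) was called by the DESeq2 Wald test. The senescence list passed upwards (1 higher and 0 lower of 20, 4 and 1 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.233 with an estimated correlation). This call was lost without WT replicates 1 (0.0992) or 2 (0.0814) or deficient replicates 1 (0.109) or 2 (0.0651; range 0.0121 to 0.233). Its called member was the cell cycle inhibitor CDKN2A at 0.70 ± 0.16, lost without WT replicate 1 (0.545) or deficient replicate 2 (0.749, range 0.00215 to 0.749) and in the DESeq2 Wald test (0.153).

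No other list was called in hNSCs, and without deficient replicate 1 only 3 of the 6 were. NRF2 targets had 1 higher of 21 (camera adjusted p = 0.892), FTH1, a ferritin chain, at 0.29 ± 0.07. FTH1 was lost without WT replicates 1 (0.0611) or 2 (0.64) or deficient replicates 1 (0.215) or 2 (0.321, range over all alternatives 0.000196 to 1), with DESeq2 size factors (0.088) and in the DESeq2 Wald test (1). Targets of p53 had 1 lower of 23 (0.595), SESN2, a stress-induced metabolic regulator, at -0.38 ± 0.10. SESN2 was lost without WT replicates 1 (0.0707) or 2 (0.487) or deficient replicates 1 (0.27) or 2 (0.207, range 0.00503 to 0.487), and in the DESeq2 Wald test (0.316). LHX2 was the 1 called of 12 forebrain and midbrain patterning genes (list adjusted p = 1). No member was called among antioxidant enzymes (0.725), nuclear-encoded respiratory chain genes (0.595), genes of Parkinson's disease and mitophagy (0.613), glycolysis and hypoxia (0.603), the cell cycle (1), apoptosis regulators (0.553), the unfolded protein response (0.595), the heat shock response (0.595), interferon-stimulated genes (0.595), cholesterol synthesis (0.595), immediate early genes (1), WNT targets (0.105) or TGF-beta and BMP targets (0.595). The same held for markers of neurons (0.595), glia (0.595), neural crest (0.595), pluripotency (0.595), bone, cartilage and fat (0.829), endothelium and blood (0.603) and epithelium and endoderm (0.806), and for HOX genes (0.595) and PARK7 neighbours (0.595).

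Among other genes that the rule named in hNSCs, ATP6AP2, an accessory subunit of the vacuolar proton pump, rose from 67.21 ± 0.85 to 122.18 ± 2.22 CPM (log2 difference 0.86 ± 0.06, adjusted p = 1.48e-12). The kinase gene MAP3K13 rose by 0.94 ± 0.11 and the zinc finger gene ZNF354C by 0.89 ± 0.15. CEBPZOS (-3.28 ± 0.22), CUTA (4.24 ± 0.50), MAGED4B (3.92 ± 0.25) and PCDHGC4 (0.86 ± 0.21) are uncertain because of overlapping genes or copies. PCDHGC4 lost its call without WT replicates 1 (0.337) or 2 (0.222) or deficient replicates 1 (0.162) or 2 (0.237, range over all alternatives 0.00486 to 0.463). OCIAD2 (log2 difference 1.28 ± 0.24) lost its call without WT replicate 2 (0.0555) or deficient replicate 1 (0.0813, range 2.71e-05 to 0.0813). ZNF283 (0.97 ± 0.22) lost its call without WT replicates 1 (0.192) or 2 (0.195) or deficient replicate 1 (0.396, range 0.00255 to 0.396). The DESeq2 Wald test called neither PCDHGC4 (0.463) nor ZNF283 (0.3). In all, 120 of 16596 genes differed by the edgeR test, 61 higher and 59 lower (1110 at an unadjusted p under 0.05), 51 of them at least 2-fold, 23 higher and 28 lower. Without deficient replicate 1 the split was 58 higher and 36 lower, and without replicate 2 it was 40 and 50. For 77.2% of tested genes the 95% interval lay within 2-fold. The DESeq2 Wald test called 69 genes and the fit of the hNSC libraries alone 215.

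Genotype effects on matrix genes differed between the lineages: COL3A1, COL1A1, COL6A2 and COL6A3 rose in deficient hMSCs and fell in deficient hNSCs. On the log2 scale the hNSC effect minus the hMSC effect was -2.88 ± 0.09 for COL3A1 (adjusted p = 4.16e-25), -2 ± 0.10 for COL1A1, -2.26 ± 0.15 for COL6A3 and -0.87 ± 0.09 for COL1A2. It was -3.60 ± 0.29 for ACTG2 and -3.20 ± 0.23 for COLEC12. COLEC12 stood at 47.74 and 136.39 CPM in WT and deficient hMSCs and at 6.57 and 2.03 CPM in hNSCs. Of the matrix list 11 of 26 genes shifted downwards and 1 upwards (14 and 3 adjusted over the list alone; camera adjusted p = 1.09e-22, and adjusted p = 0.396 with an estimated correlation). NRF2 targets also shifted downwards (5 of 21, 0 upwards; 8 and 1 adjusted over the list alone; adjusted p = 0.000104, and adjusted p = 0.427 with an estimated correlation). TKT stood at -0.46 ± 0.07 and FTL, a ferritin chain, at -0.44 ± 0.07. The unfolded protein response shifted upwards (2 of 21, 0 downwards; 4 and 0 adjusted over the list alone; adjusted p = 3.58e-06, and adjusted p = 0.396 with an estimated correlation). The 2 called were PSAT1 (1.01 ± 0.10) and ASNS (1.15 ± 0.15), of which ASNS is uncertain as above.

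TGF-beta and BMP targets had 4 of 16 genes shifted upwards between lineages and 0 downwards (7 and 3 adjusted over the list alone), with CCN2 at 0.81 ± 0.10 and CCN1 at 0.72 ± 0.10 (adjusted p = 0.015, and adjusted p = 0.54 with an estimated correlation). WNT targets had 1 of 13, CCND1 at 0.63 ± 0.07 (2 adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.396 with an estimated correlation). Targets of p53 had 1 of 23, the apoptosis effector BAX at 0.34 ± 0.09 (1 adjusted over the list alone; adjusted p = 0.0234, and adjusted p = 0.54 with an estimated correlation). The TGF-beta and BMP list was lost without WT hMSC replicate 2 (0.148), WT hNSC replicates 1 (0.108) or 2 (0.0593) or deficient hNSC replicates 1 (0.0739) or 2 (0.0855; range over all alternatives 0.00319 to 0.54). The WNT list was lost without WT hMSC replicate 1 (0.0543), deficient hMSC replicate 2 (0.0607) or WT hNSC replicate 2 (0.0593; range 0.00737 to 0.396). The p53 list was lost without WT hMSC replicate 1 (0.0543), deficient hMSC replicate 2 (0.0656) or WT hNSC replicate 1 (0.129; range 0.000944 to 0.54). BAX was lost without WT hMSC replicates 1 (0.158) or 2 (0.0856), deficient hMSC replicate 1 (0.107), WT hNSC replicate 2 (0.13) or deficient hNSC replicate 2 (0.104; range 0.0127 to 0.158), and in the DESeq2 Wald test (0.0829).

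Several genes that the rule named for this difference lay near 0 counts in hMSCs. LIMCH1 went from 0.53 to 0 CPM in hMSCs and from 84.83 to 81.9 CPM in hNSCs, and ABCC9 went from 0.68 to 0 and from 6.32 to 5.76 CPM (adjusted p = 0.0157 and 0.0311). LINGO1 went from 0.38 to 0 and from 28.42 to 30.58 CPM, and PCDH11X from 1.07 to 0.04 and from 10.11 to 11.2 CPM (adjusted p = 0.0434 and 0.00507). SOD3 (4.76 to 13.99 CPM in hMSCs, 0.56 to 0.16 CPM in hNSCs), DCN (0.33 to 0.74 and 5.97 to 1.25 CPM), DDT and MAGED4B were named as well. MAGED4B is uncertain because 100% of its windows also lie in another annotated gene, and DDT stood at 11.92 and 0.35 CPM in the 2 deficient hNSC libraries. Without WT hMSC replicate 2 the adjusted p was 0.542 for LIMCH1, 0.526 for LINGO1, 0.216 for MAGED4B and 0.0922 for DDT. Without WT hMSC replicate 1 it was 0.16 for ABCC9, 0.0622 for PCDH11X and 0.0616 for DCN. Without deficient hMSC replicate 1 it was 0.161 for LIMCH1, 0.189 for ABCC9, 0.238 for LINGO1, 0.261 for DCN and 0.0815 for DDT. Without deficient hMSC replicate 2 it was 0.0548, 0.0763 and 0.106 for LIMCH1, ABCC9 and LINGO1. Without WT hNSC replicate 1 it was 0.143 for DDT, 0.126 for SOD3 and 0.0513 for DCN. LINGO1 stood at 0.0521 without WT hNSC replicate 2, and without deficient hNSC replicate 2 it was 0.0663 for SOD3 and 0.0597 for LINGO1. LINGO1 was not called by the DESeq2 Wald test (0.0958). Over all alternatives the adjusted p ran from 0.00379 to 0.542 for LIMCH1, 0.013 to 0.189 for ABCC9, 0.0243 to 0.526 for LINGO1 and 0.00122 to 0.0622 for PCDH11X. It ran from 0.0017 to 0.126 for SOD3, 0.00139 to 0.261 for DCN, 5.38e-19 to 0.143 for DDT and 2.17e-09 to 0.216 for MAGED4B.

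The other lists did not pass the test of the difference: antioxidant enzymes (camera adjusted p = 0.334), mitochondrially encoded mRNAs (0.0999), the nuclear-encoded respiratory chain (0.334), Parkinson's disease and mitophagy (0.786), glycolysis and hypoxia (0.843), the cell cycle (0.831), senescence (0.334), apoptosis regulators (0.0999), heat shock (0.334), interferon-stimulated genes (0.863), cholesterol synthesis (0.205), immediate early genes (0.336), HOX genes (0.0999), forebrain and midbrain patterning (0.225) and PARK7 neighbours (0.547). Nor did markers of mesenchymal stem cells (0.0999), neural stem cells (0.0999), neurons (0.834), glia (0.698), neural crest (0.348), pluripotency (0.847), smooth muscle (0.966), bone, cartilage and fat (0.966), endothelium and blood (0.976) or epithelium and endoderm (0.976). The difference was called for 395 of 16596 genes, 182 upwards and 213 downwards (2061 at an unadjusted p under 0.05). The split was 233 and 167 without deficient hMSC replicate 1 and 176 and 282 without replicate 2.

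The genotype contrasts shared 50 called genes, 37 in the same direction. There were 17 higher in both, against 1.85 for independent lists of these sizes, and 12 of them, ATP6AP2 and MAP3K13 included, kept both calls whichever library was left out. There were 20 lower in both, against 1.51, and 11 of them kept both calls in the same way, among them PARK7, SYT11, FN1 and the matrix protease gene MMP14. A further 9 were higher in hMSCs and lower in hNSCs, against 1.79, and 6 kept both calls (ACTG2, COL1A1, COL3A1, COL6A2, COL6A3 and COLEC12). There were 4 lower in hMSCs and higher in hNSCs, against 1.56, and 0 kept both calls. Genes in these lists outside the naming rule were chosen after their values were seen. Those that kept both calls include CUTA, PCDHGA10, CEBPZOS and TSSC2, whose reads cannot be assigned with certainty. The contrasts share no library, but they are not independent. Per the labels, both compare the same deficient line with the same WT line, so any other difference between these lines would recur in both. Both also come from the same fit over all libraries. The excess over independent lists therefore cannot tell an effect of the loss of PARK7 from another difference between the lines.

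**Figure D4:**
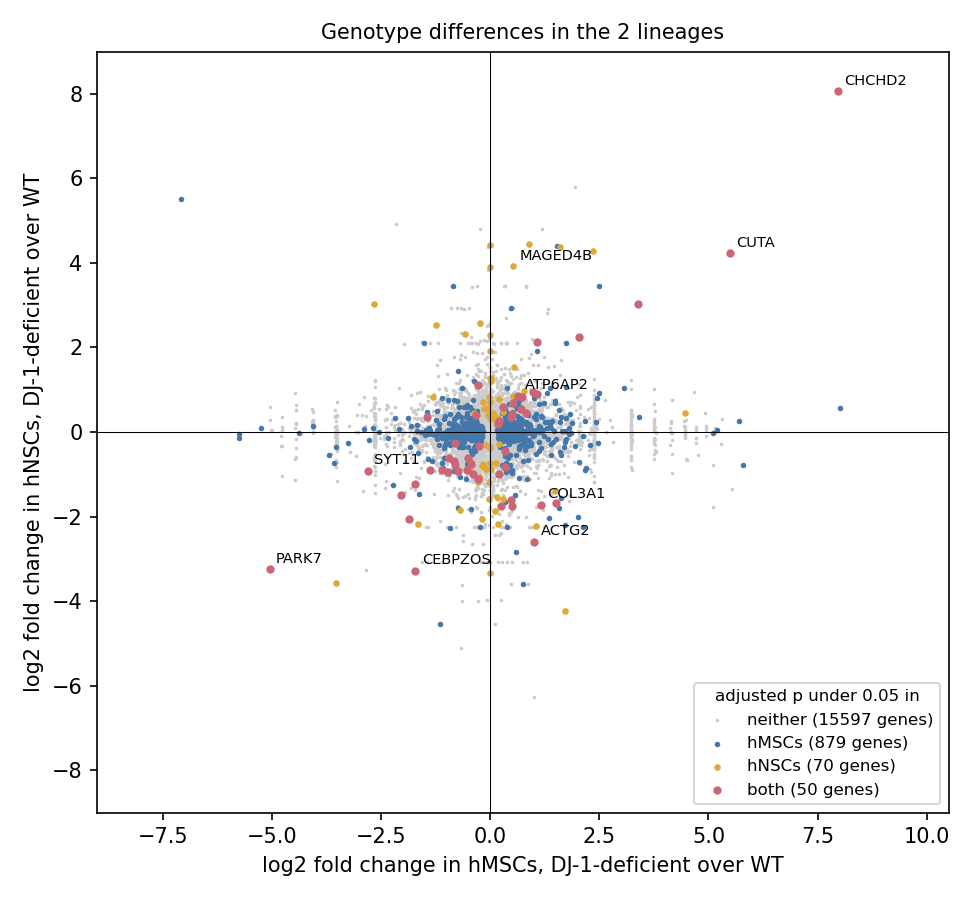
Log2 fold change of deficient over WT cells in hMSCs (x axis) and hNSCs (y axis) for the 16596 tested genes; colours mark genes with an adjusted p under 0.05 in neither lineage (15597), in hMSCs (879), in hNSCs (70) or in both (50). CHCHD2 lies at the upper right with 7.96 and 8.07, and PARK7 at the lower left with -5.05 and -3.24.

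The lineages themselves differed in most genes. Neural transcripts marked the hNSCs: DCX, which binds microtubules in young neurons, stood at 589.6 ± 21.14 CPM (SD, n = 4) in hNSCs and had 0 counts in hMSCs, so it was at least 7170-fold higher (floor of 3 counts over the 4 libraries). On the same floor the neural factor SOX3 was at least 4660-fold higher, PCDH8 3840-fold, LIN28A 3420-fold, SEMA5B 3250-fold, CRYBB1 2540-fold and LRP2 1940-fold. In the other direction SERPINB7 was at least 841-fold higher in hMSCs, ITGA8 587-fold, MYPN 568-fold and HAND2 495-fold. The collagenase MMP1 had 20088 counts in hMSCs and 1 in hNSCs (ratio 26800, 95% counting interval 4800 to 1060000) and TBX2 had 2219 and 1 (ratio 2960, 530 to 117000). TGFBI, a TGF-beta-induced matrix protein, stood at 6105.71 ± 292.26 CPM in hMSCs and 0.48 ± 0.41 CPM in hNSCs (log2 difference -13.73). The crosslinking enzyme TGM2 had a log2 difference of -12.07. These rest on 23 and 35 counts over the hNSC libraries, too few for the computed errors to hold.

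Of 19 neural stem cell markers 18 were higher in hNSCs and 0 lower (camera adjusted p = 1.2e-14). The transcription factors PAX6 and SOX2 stood at 8.57 and 10.72 on the log2 scale, with only 43 and 10 counts over the hMSC libraries. Errors are left out for markers with few counts in 1 lineage, because the computed ones are too small there. With an estimated correlation none of the 23 lists called between lineages was called (adjusted p = 0.162 to 0.373). Neural stem cell markers (camera adjusted p = 0.162) were among those lost. This form of the test could therefore hardly call any list here, and its lack of calls cannot decide which lists differ. All 17 neuron markers were higher (1.59e-08), such as the neurofilament NEFM (6.51, 208 counts in hMSCs) and MAP2 (6.41, 156 counts in hMSCs). Of 19 mesenchymal markers 17 were lower and 2 higher in hNSCs (9.42e-13). The surface proteins NT5E and CD44 stood at -9.83 and -8.22, with 43 and 201 counts over the hNSC libraries. Of 26 matrix genes 23 were lower and 3 higher (8.79e-22), with COL1A1 at -8.31 ± 0.05 and FN1 at -6.51 ± 0.04. Smooth muscle markers (10 of 12 lower, 4.76e-08), epithelial and endoderm markers (7 of 9 lower, 0.000612), TGF-beta and BMP targets (13 of 16 lower, 3 higher, 1.96e-08), the senescence list (16 of 20 lower, 2 higher, 4.94e-07) and NRF2 targets (18 of 21 lower, 3 higher, 2.77e-07) were lower in hNSCs as groups. So were glycolysis and hypoxia (21 of 24 lower, 2 higher, 8.12e-09), p53 targets (17 of 23 lower, 2 higher, 0.000277), the unfolded protein response (16 of 21 lower, 4 higher, 6.45e-05), and heat shock (11 of 14 lower, 1 higher, 0.000444). The same held for immediate early genes (13 of 17 lower, 3 higher, 0.000721), Parkinson's disease and mitophagy (15 of 21 lower, 4 higher, 0.00237), antioxidant enzymes (14 of 19 lower, 3 higher, 0.00476), the nuclear-encoded respiratory chain (20 of 30 lower, 2 higher, 0.0117) and mitochondrially encoded mRNAs (11 of 13 lower, 1 higher, 0.0496). Before normalization, mitochondrial genes took 2.95% to 3.32% of gene counts in hMSCs and 2.98% to 3.37% in hNSCs. Their lower levels in hNSCs thus depend on the TMM factors, 0.853 to 0.896 in hMSCs and 1.135 to 1.147 in hNSCs. Higher in hNSCs as groups were the cell cycle (23 of 28 higher, 2 lower, 0.000127), cholesterol synthesis (18 of 20 higher, 1 lower, 6.16e-05), pluripotency markers (5 of 6 higher, 1 lower, 0.000396), forebrain and midbrain patterning (9 of 12 higher, 3 lower, 0.0281) and WNT targets (10 of 13 higher, 3 lower, 0.0481). Adjusted over the list alone, the counts of all these lists were the same.

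Not called between lineages were apoptosis regulators (0.238), interferon-stimulated genes (0.277), HOX genes (0.152), PARK7 neighbours (0.292) and markers of glia (0.739), neural crest (0.385), bone, cartilage and fat (0.681) and endothelium and blood (0.323). Without single hMSC libraries (WT replicates 1 and 2, then deficient replicates 1 and 2), the adjusted p was 0.0622, 0.0861, 0.0919 and 0.0671 for forebrain and midbrain patterning (range over all alternatives 0.0243 to 0.257). In the same order it was 0.215, 0.255, 0.191 and 0.17 for mitochondrially encoded mRNAs (0.00058 to 0.373), 0.0883, 0.144, 0.131 and 0.125 for the nuclear-encoded respiratory chain (9.38e-06 to 0.162), and 0.151, 0.255, 0.384 and 0.34 for WNT targets (0.0392 to 0.384). With DESeq2 size factors these 4 lists were not called (0.0509, 0.13, 0.0524 and 0.113). Without the filter on low counts forebrain and midbrain patterning (0.0502), WNT targets (0.0516) and pluripotency markers (0.106) were not, and with protein-coding genes only the mitochondrially encoded mRNAs (0.0869) and WNT targets (0.0604) were not. In the edgeR test 13806 of 16596 genes, or 83.19%, differed between lineages, 7328 higher and 6478 lower in hNSCs. Lineage went together with medium and passage, and with a prefix in the column headers of the hMSC files.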

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

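The tests of CHCHD2 and of RNA carried over from hMSCs were chosen only after the results were seen, while the tests of a contaminating cell type, of near-identical copies and of other groupings of the libraries were written down before. Of 119 named genes, 58 had genotype effects that differed between the lineages by the interaction test, and 6 gene lists differed as well. Over all 16596 tested genes it was 395, or 2.38%. The named genes had been picked for a call in 1 lineage or in the interaction test itself, which raises their share. The values below are the effect in hNSCs minus the effect in hMSCs on the log2 scale.

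The effect was lower in hNSCs than in hMSCs for ACTG2 -3.60, SOD3 -3.36, DCN -3.28, COLEC12 -3.20, COL3A1 -2.88, COL6A3 -2.26, PRRX1 -2.08, COL1A1 -2, COL16A1 -1.87, PDGFRA -1.74, CYP1B1 -1.69, BGN -1.55, PDGFRB -1.17, COL1A2 -0.87, MYLK -0.73, IGFBP5 -0.67 and COL6A1 -0.56. The same direction held for the NRF2 targets NQO1 -0.63, SLC7A11 -0.55 and TKT -0.46, and for DDT -5.13, PWWP3B -2.74, CALHM2 -2.27, SOX5 -1.91, MTUS1 -1.88, TMEM132D -1.71, CEBPZOS -1.56, DLK1 -1.41, IRX3 -1.30, MSX2 -1.10 and BCL2L11 -0.81. The MSX2 difference was lost without WT hMSC replicates 1 (0.0772) or 2 (0.0516), deficient hMSC replicate 1 (0.0669), WT hNSC replicate 1 (0.423) or deficient hNSC replicate 1 (0.251; range of the adjusted p over all alternatives 0.023 to 0.423). BCL2L11 was lost without WT hMSC replicate 1 (0.121) or deficient hMSC replicate 1 (0.1; range 0.00161 to 0.121), and IRX3 without WT hMSC replicate 1 (0.0622; range 0.00216 to 0.0622).

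The other direction held for CCN2 0.81, CCN1 0.72, PMEPA1 0.60, the matrix list member THBS1 0.58, ASNS 1.15, PSAT1 1.01, PCDH11X 4.20, MAGED4B 3.39, TIMM23B 3.17, SYT11 1.89, FAM156B 1.86, PARK7 1.81, TENM2 1.68, OCIAD2 1.25, RELN 1.17, CDH2 0.81, CFLAR 0.71, LDHA 0.69, CCND1 0.63, CALD1 0.46, MT-ND4L 0.43 and STMN2 0.33. MT-ND4L was lost in the DESeq2 Wald test (0.497) and without WT hMSC replicate 1 (0.139), deficient hMSC replicate 1 (0.125), WT hNSC replicate 2 (0.0582) or deficient hNSC replicate 2 (0.0773, range of the adjusted p over all alternatives 1.69e-05 to 0.497). PMEPA1 was lost in the DESeq2 Wald test (0.0958) and without WT hMSC replicate 2 (0.212), deficient hMSC replicate 1 (0.13), WT hNSC replicate 1 (0.131) or deficient hNSC replicate 1 (0.0687, range 0.00994 to 0.212). The losses of DDT, SOD3, DCN, PCDH11X, MAGED4B, LIMCH1, ABCC9 and LINGO1 stand in the report. TIMM23B and FAM156B are uncertain here too. In the 2 WT hMSC libraries TIMM23B stood at 2.08 and 26.68 CPM, and FAM156B at 23.48 ± 20.68 CPM (mean and SD). LIMCH1, ABCC9 and LINGO1 had 0 counts in deficient hMSCs, so only the adjusted p is given: 0.0157, 0.0311 and 0.0434. The lists that differed were NRF2 targets (adjusted p = 0.000104), p53 targets (0.0234), the unfolded protein response (3.58e-06), the extracellular matrix (1.09e-22), WNT targets (0.015) and TGF-beta and BMP targets (0.015). With an estimated correlation none of these 6 lists was called (adjusted p = 0.396 to 0.54).

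CHCHD2 was near 0 in all 4 WT libraries and at 107.23 CPM or more in all 4 deficient libraries. Reads assigned to its pseudogenes did not account for this, since CHCHD2 and its 10 relatives together reached 0.434% of the deficient level in WT libraries. A mislabelled library did not either, since 0 libraries lay on the other genotype's side for PARK7 or CHCHD2. A difference between cell lines other than the loss of DJ-1 could not be told apart from an effect of that loss, because the labels name 1 deficient line.

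Matrix genes were lower in deficient hNSCs. RNA carried over from hMSCs into the WT hNSC libraries was excluded as the sole cause, because 9 of 50 abundant hMSC genes, such as TGFBI (0.67 CPM against 24.48 CPM needed), lay under 50% of the level that the COL1A1 excess would need. A first test of the median excess, 15.6% of that of COL1A1, had fallen between its bounds and was replaced by this one. Fewer cells of 1 contaminating mesenchymal type in the deficient cultures would lower its genes alike; the 15 genes tested fell by unlike amounts (Cochran's Q against chi-square, n = 15 genes, p = 9.66e-69), but this could not exclude it, and the bound written before was wrong, because deficient hNSCs still held these transcripts (FN1 at 377.41 CPM and COL1A2 at 55.44 CPM), and expression of their own would dilute the fall unevenly. An effect of genotype on the hNSCs themselves could not be told apart from it.

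There were 14 features that differed over 8-fold between the 2 libraries of a group, TIMM23B and DDT among them. Of the 10 with a transcript sequence, 5 shared at least 50% of their windows with another gene, against 3.63% of 965 other genes (Fisher exact p = 1.96e-05), so reads shared with a near-identical copy likely account for part of them. MICA, ABCF1, RPS18, TIMM23B and DDT shared less, and nothing else was tested for them. No biological explanation was tested.

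When the 8 libraries were split 4 against 4 in every way, 1 of 35 splits, the one by lineage, called as many genes as that split (13467). The highest count of another split was 1, and the split by genotype also called 1. Every other split mixes the lineages within a side, so few calls were bound to follow and the comparison adds no evidence.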

How the results depend on the processing

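Only 1 alternative was chosen after the data were seen, the fit without features that differed over 8-fold between replicates. No call of a list or of a gene named by the rule changed direction under any alternative. Among all called genes 1 did: RPS18, which differed over 8-fold between the deficient hNSC libraries, went from a log2 difference of 2.31 in hNSCs to -2.95 without deficient replicate 2 (adjusted p = 0.0121). With a 2-fold minimum, by construction, 168 genes were called in hMSCs, 51 in hNSCs, 135 for the difference between lineages and 7678 between lineages. The DESeq2 Wald test called 589 genes in hMSCs and 69 in hNSCs, and the fit of each lineage alone 215 in hNSCs. The cause was not tested. The percent of genes bounded within 2-fold (71.5% in hMSCs and 77.2% in hNSCs) was 55.5% and 45.5% without a filter, which adds weakly expressed genes, 80.3% and 85.3% for protein-coding genes only. It was 65.1% and 70.5% with the DESeq2 Wald test and 82.6% and 82.8% with each lineage alone; for the latter pair the cause was not tested. With an estimated correlation the lists called went from 7 (hMSCs), 6 (hNSCs), 6 (difference) and 23 (lineage) to 0 in each, and in total from 42 to 0. Even neural stem cell markers between lineages were lost (camera adjusted p = 0.162), so these losses cannot decide which list calls hold.

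Replicate numbers did not pair the libraries: the correlation of replicate differences between genotypes was -0.051 in hMSCs and -0.013 in hNSCs. With the replicate number as a block, 830 genes were called in hMSCs, 114 in hNSCs, 336 for the difference and 13777 between lineages, and 70.8% and 76.5% were bounded. In the same order 122, 13, 68 and 75 calls were lost, MT-CO3 in hMSCs (edgeR adjusted p = 0.0623) among them. The call of the matrix list in hMSCs was lost as well.

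With 1 library left out, the called genes ranged from 559 to 1060 in hMSCs, 88 to 154 in hNSCs, 282 to 458 for the difference and 13669 to 14132 between lineages, and the shared calls from 30 to 42. The bounded percent ranged from 63.8% to 68.8% in hMSCs and from 68.1% to 74% in hNSCs, PARK7 from -5.25 to -4.77 and from -3.28 to -3.20. The lists called ranged from 6 to 8 in hMSCs, 3 to 6 in hNSCs, 4 to 7 for the difference, 19 to 23 between lineages and 35 to 40 in total; the lowest in hNSCs was without deficient replicate 1. Fewer libraries were fitted in each. Of the named genes, 34 of 89 in hMSCs, 11 of 37 in hNSCs, 21 of 45 for the difference and 0 of 135 between lineages lost their call without some library. In hMSCs, 54.3% of called genes were higher, and 41.4% and 66.8% without deficient replicates 1 and 2. Without the features that differed over 8-fold, 953, 125, 416 and 13813 genes were called. DESeq2 size factors (1005, 113, 449 and 13842), no filter (883, 171, 421 and 15308) and protein-coding genes only (1057, 112, 481 and 11680) kept these counts within 1.5 times. Between 7037075 and 14855976 gene counts per library limit what can be seen in weakly expressed genes.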

Other observations

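No test in this part was chosen after its result was seen. The median log2 fold change per nuclear chromosome lay between -0.02 (chromosome 13) and 0.04 (chromosome 17) in deficient against WT hMSCs and between -0.01 (chromosome 19) and 0.02 (chromosome 5) in hNSCs; 3 copies in place of 2 would give 0.58. For mitochondrial genes the median was 0.14 in hMSCs and 0.16 in hNSCs. Over the 2000 genes of highest variance across the 8 libraries, the first principal component held 97.7% of the variance and separated the lineages. This is not the share over all genes, because genes that differ between lineages are favoured by that choice.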
